A study of Mus musculus with 60 samples.

How the data were processed

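Liver RNA of 60 mice was measured on Affymetrix expression arrays, 1 animal per array. Per the labels the animals were male C57BL/6J mice of 12 to 15 weeks carrying 1 of 3 transgenic variants of the aryl hydrocarbon receptor (AHR, the receptor that binds dioxins), named rWT, DEL and INS. Each received a single oral gavage of 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD) in corn oil at 125, 250, 500 or 1000 µg/kg, or corn oil alone, and the liver was taken after 4 days (96 hours). What distinguishes the receptor variants is not given in the sources used here.

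The deposited values are log2 expression values, 1 feature per Entrez gene. Per the labels the authors processed the arrays with RMA in R 3.1.2 with affy 1.44.0. The background correction, the probe-set definition and the genome build are not given in the sources used here. All 21115 deposited features were used as they stand, with no further scaling and no filter. Of these, 20405 carried 1 gene symbol, 0 carried several and 710 carried none, and 1241 were predicted genes, which were tested but not named. No sample lay outside the 15 groups.

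The array levels followed the line: array mean log2 was 6.01 to 6.07 in rWT, 6.23 to 6.30 in DEL and 5.58 to 5.74 in INS, and the array medians of INS (5.22 to 5.38) lay below all of rWT (5.65 to 6.01) and DEL (5.81 to 6.25). Normalizing each line on its own would leave such a pattern, but whether this was done is not given in the sources used here. Other differences in handling between the lines cannot be told apart from it. Comparisons of TCDD with corn oil stay within a line, so a constant offset between lines cancels in them and in the differences between them. A change of scale between lines would not cancel, and those differences are also given after quantile normalization across all arrays where the count or its split moved. Corn oil differences between lines carry the offset and any change of scale. The median difference over all features is given with them, and named genes of INS minus DEL are also given relative to it. Those against rWT are given as fitted. The array maxima did not follow the line (13.6 to 13.8), so the offset is not the same at every level and a median does not remove it in full.

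The choices in this paragraph were made before the data were examined. One linear model with a mean for each of the 15 groups was fitted over the 60 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; two-sided moderated tests). Its contrasts were TCDD against corn oil in each line, averaged over the 4 doses and at each dose; the slope of the TCDD groups on log2 dose; the difference between lines in the averaged TCDD effect; and the difference between lines in corn oil mice. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes and is not moved by a shift common to all genes, and again with the correlation estimated for each list, with adjustment over the 35 lists. Effects are log2 differences ± standard error (SE) of the fit, and levels are group means ± standard deviation (SD).

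The 35 lists held 725 members, of which 665 were measured. The pathway lists were AHR target genes, NRF2 target genes, CAR and PXR target genes, bile acid synthesis and transport, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation and PPARA targets, lipid uptake storage and export, glucose metabolism, urea cycle and amino acid catabolism, iron and haem metabolism, circadian clock, male-biased and female-biased liver genes, acute phase proteins, coagulation and complement, cytokines and chemokines, interferon-stimulated genes, cell cycle, p53 targets and growth arrest, endoplasmic reticulum and integrated stress response, heat shock and protein folding, oxidative phosphorylation, and pericentral and periportal hepatocyte genes. The cell type lists were markers of hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils, stellate cells and matrix, endothelium, cholangiocytes, erythroid cells, pancreas and adipocytes.

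Genes are named by a rule fixed at the same time. It took features with 1 symbol, left out predicted genes and used the feature with the highest mean. It covers Ahr, Cyp1a1, Cyp1a2, Cyp1b1, Tiparp, Ahrr, Nqo1 and Aldh3a1 everywhere. For each line it adds the 10 largest rises and the 10 largest falls of the averaged effect among called genes with 1 sign at all 4 doses. For each difference between lines, corn oil difference and dose slope it adds the 5 largest called estimates in each direction. For each list it adds up to 4 called members with the largest effect, or the 2 largest as values where none was called. A gene named for 1 line may be given in the others. Exceptions, chosen after their values were seen, are the sex-linked genes Xist, Eif2s3y, Uty and Kdm5d and some genes called in all 3 lines in the last part.

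Alternatives chosen at the same time were quantile normalization across the 60 arrays, median centring of each array, a filter on features above the 40th percentile of mean log2, a minimum absolute log2 change of 1, array weights, a prior variance with trend and robust estimation, the replicate number as a block, only the arrays of the lines compared, 1 feature per gene symbol, and leaving out each array in turn. Chosen after seeing the data were a fit without 4 rWT arrays whose sex-linked genes go against their label, and a fit with that pattern as a covariate. Median centring moves the median TCDD effect over all features from -0.07 to -0.29 in rWT, from -0.05 to -0.31 in DEL and from -0.01 to -0.03 in INS, and quantile normalization moves it to -0.02, -0.03 and -0.01. Replicate numbers carried no pairing: after removing group means, correlations between corn oil and TCDD arrays with equal numbers were -0.45 to 0.35 over the 12 comparisons checked, so no pairs were formed.

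The number of arrays (2 to 5 per group) limits the precision. In simulated data of the same design with 200 changed features, a log2 change of 0.5 was recovered for 62.7% of features in rWT, 56.7% in DEL and 50.7% in INS. At a log2 change of 1 the share was 91.0%, 94.0% and 86.6%, and at a change of 2 it was 100%, 98.5% and 98.5%. The simulated noise was normal, independent between features and equal in all lines, so structure among the samples was not covered. Contrasts with far more changed features also have another threshold under the adjustment.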

Results

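The data are 60 liver arrays in 15 groups. The rWT line had 5 corn oil mice and 3, 3, 4 and 2 mice at 125, 250, 500 and 1000 µg/kg TCDD. The DEL line had 5 corn oil mice and 4 mice at each dose, and the INS line had 5 corn oil mice and 4, 4, 4 and 5 mice in the same order of doses. The comparisons ask how the liver transcriptome of each AHR-variant line responded to TCDD, whether the response depended on dose, and whether it differed between lines.

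A check of sex-linked genes set 4 rWT arrays apart from their label. Xist, the RNA expressed from the inactive X chromosome, read 10.7 to 11.4 on corn oil replicates 3, 4 and 5 and on TCDD 500 replicate 4, against 2.41 to 3.44 on the other 56 arrays. The Y-linked genes were low on the same 4 arrays and high on the rest: Eif2s3y read 2.73 to 3.37 against 8.15 to 9.72, Uty 3.03 to 3.81 against 7.24 to 8.52, and Kdm5d 3.74 to 4.10 against 6.25 to 7.97. All 4 arrays are labelled male. They make up 3 of the 5 rWT corn oil arrays, so values without them are given beside the rWT results whose call they change. TCDD 500 replicate 4 also carried 21.9% of the average rWT response, where the other 11 treated rWT arrays carried 80.7% to 111%. That response was the mean of those other treated arrays minus the mean of all 5 corn oil arrays. It therefore holds part of the sex difference, which lowers the share of this array. Cyp1a1 read 13.1 and Tiparp 10.7 on it, near the other treated rWT arrays, whereas Gpnmb (7.49) lay below all of them. Nqo1 (9.97, against 11.4 to 12.2) and Ahrr (8.26, against 8.48 or more) also lay below all the other treated rWT arrays.

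**Figure D1:**
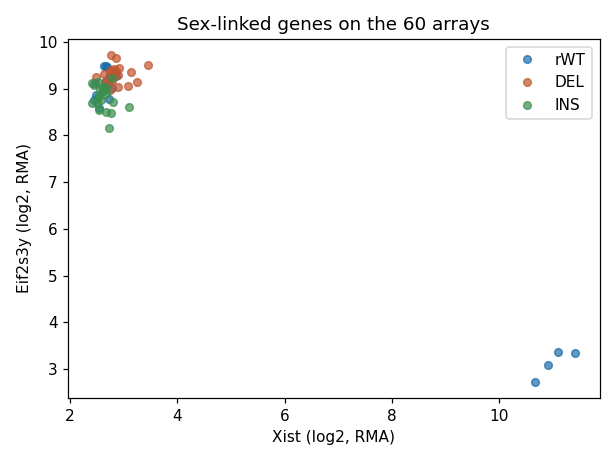
Log2 expression of Xist against the Y-linked Eif2s3y, 1 point per array, for the 60 arrays by line. The 4 rWT arrays with Xist of 10.7 to 11.4 have Eif2s3y of 2.73 to 3.37, and the other 56 have Eif2s3y of 8.15 to 9.72.

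In rWT mice, lists of AHR targets, cell cycle genes and macrophage and neutrophil markers were called higher under TCDD, and lists of bile acid, lipid and amino acid metabolism lower. With all arrays, only the AHR target list kept its call when the correlation between genes was estimated. Cyp1a1 (Entrez 13076, chromosome 9), the classical AHR-driven monooxygenase gene, rose by 6.19 ± 0.19 (adjusted p = 1.18e-30), from 6.67 ± 0.81 (SD, n = 5) in corn oil to group means of 12.8 to 12.9, and every treated array (lowest 12.7) lay above every corn oil array (highest 7.84). Cyp1b1 (13078, chromosome 17) rose by 7.26 ± 0.28, and the AHR repressor gene Ahrr (11624, chromosome 13) by 5.03 ± 0.25. Nqo1 (18104, chromosome 8), a quinone reductase, rose by 3.73 ± 0.29, the ADP-ribosyltransferase gene Tiparp (99929, chromosome 3) by 3.50 ± 0.22, and Cyp1a2 (13077, chromosome 9), already at 12.3 in corn oil, by 1.19 ± 0.09. Ahr itself (11622, chromosome 12; 0.24 ± 0.11, adjusted p = 0.0790) and Aldh3a1 (11670, chromosome 11; 0.06 ± 0.16, adjusted p = 0.805) did not pass. Without the 4 rWT arrays set apart above, the rises were 5.59 for Cyp1a1, 6.43 for Cyp1b1, 4.81 for Ahrr, 4.73 for Nqo1, 3.97 for Tiparp and 0.70 for Cyp1a2.

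Other large rises in rWT were Gpnmb, a glycoprotein of lipid-laden macrophages (7.04), the cytochrome gene Cyp21a1 (6.55), the matrix metalloproteinases Mmp8 (5.79) and Mmp12 (5.28), Sprr1a (5.77), the monocyte chemokine Ccl7 (5.69), Ecel1 (5.39) and the decoy receptor of interleukin-1, Il1r2 (5.22). The largest falls with all arrays were Sult2a8 (-6.27) and Inmt (-6.05), the carbonic anhydrases Car3 (-5.85) and Car1 (-5.43), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-5.62). They were followed by Mmd2 (-5.17), Cyp4f14 (-5.09), the peroxisomal hydroxyacid oxidase gene Hao1 (-5.07), Upp2 (-4.87) and Ces3b (-4.85). This ranking depends on the 4 arrays set apart above. Without them the male-biased genes Hsd3b5 and Serpina4-ps1 fell much further, as given below. In all, 8584 of 21115 features were called in rWT by limma, 4284 higher and 4300 lower. Leaving out the 4 arrays, 7612 were called, of which 5994 were shared, and with the female pattern as a covariate 5753. The split of the count depends on scaling: median centring, which shifts all genes down in TCDD arrays, gave 13735, of which 2782 were higher and 10953 lower.

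By gene list, AHR targets rose in rWT: 11 of 16 measured rose, 0 fell and 5 did not pass, 11 when adjusted over the list alone, with a median of 1.30 (camera adjusted p = 4.46e-14, and 3.14e-05 with an estimated correlation). In all, 21 lists were called in rWT at the preset correlation. NRF2 targets, the antioxidant response, had 16 rises and 1 fall among 22 (17 and 1 adjusted over the list alone; median 0.94, adjusted p = 1.07e-09; adjusted p = 0.123 with an estimated correlation). Among them were the cystine transporter gene Slc7a11 (4.56), Srxn1 (2.72), Abcc4 (2.30) and haem oxygenase Hmox1 (1.94). Of 26 cell cycle genes 25 rose and 1 did not pass, 25 also when adjusted over the list alone, with a median of 2.01 (adjusted p = 5.48e-20; adjusted p = 0.123 with an estimated correlation). Ccna2 (3.81), Ccnb2 (3.58), Aurkb (3.40) and Foxm1 (3.33) led it. The p53 targets and growth arrest list had 10 rises and 2 falls among 19, both when adjusted over all genes and adjusted over the list alone (median 0.57, adjusted p = 0.00222; adjusted p = 0.123 with an estimated correlation). The largest changes were the cell cycle inhibitor Cdkn1a (4.06), Tnfrsf10b (3.24) and Gadd45b (2.62).

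Markers of neutrophils, macrophages and stellate cells were called higher in rWT. Neutrophil markers had 9 rises and 0 falls among 13 (9 adjusted over the list alone; median 3.18, adjusted p = 6.32e-08; adjusted p = 0.0806 with an estimated correlation). With the 4 arrays left out, the call also held with an estimated correlation (adjusted p = 0.00897). Among the rises were Mmp8 (5.79), S100a8 (4.56), Retnlg (4.53) and Mmp9 (4.27). Kupffer cell and macrophage markers had 14 rises and 1 fall among 19 (15 and 2 adjusted over the list alone; median 1.15, adjusted p = 4.42e-09; adjusted p = 0.123 with an estimated correlation). Among them were Gpnmb (7.04), Itgam (3.96), the lipid receptor Trem2 (3.39) and Cd68 (1.82). Stellate cell and matrix markers had 14 rises and 1 fall among 19 (15 and 1 adjusted over the list alone; median 1.54, adjusted p = 1.74e-08; adjusted p = 0.123 with an estimated correlation). Among them were Lox (3.76), Timp1 (3.67), Tagln (2.91) and Acta2 (2.87). Cytokines and chemokines had 14 rises and 2 falls among 24, also adjusted over the list alone (median 0.85, adjusted p = 2.22e-05; adjusted p = 0.217 with an estimated correlation). Among them were Ccl7 (5.69), Ccl3 (5.04), Ccl2 (4.42) and Cxcl2 (3.14). Endothelial markers (8 rises and 2 falls among 16, also adjusted over the list alone; median 0.41, adjusted p = 0.0783) did not pass. Hepatocyte markers moved little, with 1 rise and 5 falls among 12 (1 and 6 adjusted over the list alone) and a median of -0.06 (adjusted p = 0.0892). The largest was Cyp2e1 (-0.88).

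Several metabolic lists were called lower in rWT. Of 27 urea cycle and amino acid catabolism genes 22 fell and 1 rose (23 and 1 adjusted over the list alone; median -1.34, adjusted p = 1.93e-12; adjusted p = 0.123 with an estimated correlation). Among them were the urea cycle enzyme Otc (-4.49), Haao (-2.82) and Uroc1 (-2.49). Bile acid synthesis and transport had 20 falls and 1 rise among 26, also adjusted over the list alone (median -1.16, adjusted p = 3.75e-08; adjusted p = 0.123 with an estimated correlation). Among them were Cyp7a1 (-5.62), the uptake transporter Slco1a1 (-4.17), Akr1d1 (-3.08) and Slc27a5 (-2.87). Fatty acid and triglyceride synthesis had 18 falls and 1 rise among 22 (19 and 1 adjusted over the list alone; median -1.17, adjusted p = 1.19e-08; adjusted p = 0.123 with an estimated correlation). Among them were Thrsp (-3.48), Elovl2 (-3.27) and the lipogenic transcription factor Srebf1 (-2.23). Cholesterol synthesis had 13 falls and 0 rises among 20 (15 falls adjusted over the list alone; median -0.79, adjusted p = 1.11e-05; adjusted p = 0.314 with an estimated correlation). Among them were Sc5d (-1.80), Stard4 (-1.65), Insig1 (-1.65) and Dhcr7 (-1.60). Coagulation and complement had 22 falls and 1 rise among 26 (23 and 1 adjusted over the list alone; median -0.93, adjusted p = 6.09e-10; adjusted p = 0.125 with an estimated correlation). Among them were Mbl2 (-3.12), C9 (-2.72), C8a (-2.49) and F7 (-2.28).

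Further lists were called lower in rWT. CAR and PXR targets had 9 falls and 1 rise among 16, also adjusted over the list alone (median -0.89, adjusted p = 0.00160; adjusted p = 0.192 with an estimated correlation). Among them were Ces2a (-2.81) and Gstt1 (-1.99). Pericentral hepatocyte genes had 11 falls and 1 rise among 15, also adjusted over the list alone (median -0.88, adjusted p = 0.00203; adjusted p = 0.294 with an estimated correlation). Cyp2c50 (-2.71) fell most, and the 1 rise was the amino acid transporter Slc1a4 (3.07). Erythroid markers had 5 falls among 7, also adjusted over the list alone (median -1.07, adjusted p = 0.00626; adjusted p = 0.212 with an estimated correlation). Among them were Hbb-bt (-2.37) and Alas2 (-2.28). Periportal genes (7 falls and 2 rises among 15, 8 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.0398; adjusted p = 0.286 with an estimated correlation), oxidative phosphorylation (10 falls among 28, 9 adjusted over the list alone; median -0.22, adjusted p = 0.00915; adjusted p = 0.448 with an estimated correlation) and adipocyte markers (4 falls among 7, also adjusted over the list alone; median -0.78, adjusted p = 0.00817; adjusted p = 0.125 with an estimated correlation) lost their call without the 4 arrays. A call lost in this smaller set of arrays does not show that no fall remained. Car3 (-5.85, and -6.48 without the 4 arrays) led the adipocyte list and is also a liver gene, while Retn (-1.16) was 0.01 without the 4 arrays.

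Of the 2 sex-biased lists, the female-biased one followed the sex pattern of the corn oil arrays. The male-biased one did not, as it fell with all arrays and fell further without the 4. Female-biased liver genes had 16 falls and 1 rise among 21 in rWT (17 and 1 adjusted over the list alone; median -1.74, adjusted p = 0.000156; adjusted p = 0.327 with an estimated correlation). Among them were Cyp2b13 (-4.44) and Cyp2b9 (-4.20). Without the 4 arrays 6 rose and 5 fell, the median was -0.27 and the mean 0.09, and the list was not called (adjusted p = 0.951). Cyp2b13 then stood at -0.36 and Cyp2b9 at -1.24, neither called, while Cyp17a1 (-3.80, and -2.47 without the 4) was called either way. Male-biased liver genes had 12 falls and 2 rises among 19 (13 and 2 adjusted over the list alone; median -0.98, adjusted p = 0.00349; adjusted p = 0.374 with an estimated correlation). With those arrays left out, 17 of the 19 fell and 0 rose, with a median of -2.06 (adjusted p = 2.12e-08; adjusted p = 0.0894 with an estimated correlation), and Hsd3b5, a male-specific steroid dehydrogenase, went from -3.29 to -8.06 and Serpina4-ps1 from -3.24 to -6.33.

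The remaining lists were not called in rWT with all arrays. They were fatty acid oxidation and PPARA targets (2 rises, 12 falls of 23, median -0.38, adjusted p = 0.0770), lipid uptake storage and export (8 rises, 3 falls of 24, median -0.12, mean 0.27), glucose metabolism (6 rises, 9 falls of 20, median -0.23), iron and haem metabolism (6 rises, 8 falls of 22, median near 0, mean -0.13) and circadian clock (1 rise, 6 falls of 18, median -0.57). So were acute phase proteins (6 rises, 10 falls of 25, mean 0.08 with the camera direction down), interferon-stimulated genes (7 rises, 4 falls of 21, median 0.12), the endoplasmic reticulum and integrated stress response (7 rises, 3 falls of 24, median 0.02), heat shock and protein folding (2 rises, 3 falls of 12, median 0.10, mean -0.05) and lymphocyte markers (5 rises, 5 falls of 19, median 0.06). Cholangiocyte markers (2 rises, 1 fall of 11, median -0.16) and pancreas markers (1 rise, 5 falls of 11, median -0.99) complete them. Adjusted over the list alone, the rises and falls were 2 and 12, 8 and 3, 7 and 10, 8 and 9, 1 and 6, 8 and 10, 7 and 5, 7 and 3, 2 and 3, 5 and 5, 2 and 0, and 1 and 6, in the same order. Without the 4 arrays the endoplasmic reticulum and integrated stress response list was called higher, with 6 rises and 0 falls, also adjusted over the list alone (median 0.23, adjusted p = 0.00533; adjusted p = 0.153 with an estimated correlation). Fatty acid oxidation and PPARA targets then had 3 rises and 4 falls with a median of -0.05 and a mean of 0.10 (adjusted p = 0.938), and pancreas markers had 1 rise and 3 falls with a median of -0.24 and a mean of 0.34 (adjusted p = 0.951). Falls also became fewer in the circadian clock (2), glucose metabolism (7) and acute phase protein (7) lists, none of them called. Single arrays mattered too: the calls of the pancreas genes Cpb1 and Try5 in rWT were each lost in 1 of 17 omissions of single rWT arrays. Single members moved far: the hepatokine Fgf21 rose by 3.41, the serine synthesis gene Psat1 by 5.01, lipocalin Lcn2 by 3.69, the lipid droplet gene Cidec by 3.12 and Igfbp1 by 2.60, while the glucose transporter Slc2a2 fell by 3.63.

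In DEL mice the response resembled that of rWT. Cyp1a1 rose by 4.80 ± 0.18 (adjusted p = 1.61e-26), from 8.13 ± 0.48 (SD, n = 5) to group means of 12.90 to 12.97, with every treated array (lowest 12.8) above every corn oil array (highest 8.63). Cyp1b1 rose by 6.52 ± 0.27, Ahrr by 4.301 ± 0.243, Tiparp by 3.88 ± 0.21, Nqo1 by 3.76 ± 0.28 and Cyp1a2 by 0.70 ± 0.09. Ahr (0.11 ± 0.11, adjusted p = 0.433) and Aldh3a1 (0.05 ± 0.15, adjusted p = 0.841) did not pass. Other large rises were Gpnmb (6.32), Mmp12 (5.19), the glucuronosyltransferase Ugt1a7c (5.16), the chymotrypsinogen gene Ctrb1 (5.09), Sprr1a (4.90), Ecel1 (4.86), the carbonyl reductase Cbr3 (4.81) and Psat1 (4.41). The largest falls were Hsd3b5 (-7.01), Slco1a1 (-4.91), Serpina4-ps1 (-4.75), Car1 (-4.69), the receptor gene Adgrf1 (-4.51), Sult2a8 (-4.45), the fatty acid elongase Elovl3 (-4.07), Car14 (-3.96), Inmt (-3.88) and the succinate receptor Sucnr1 (-3.86). In all 7245 features were called, 3519 higher and 3726 lower. Median centring gave 13835, of which 2186 were higher and 11649 lower.

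AHR targets rose in DEL for 13 of 16 with 0 falls, also adjusted over the list alone (median 1.46, adjusted p = 5.70e-17, and 5.02e-06 with an estimated correlation). Kupffer cell and macrophage markers rose for all 19 measured, also adjusted over the list alone (median 1.73, adjusted p = 2.70e-22, and 0.0111 with an estimated correlation). Among them were Gpnmb, Trem2 (3.45), Itgam (2.44) and the chemokine receptor Cx3cr1 (2.43). All 26 cell cycle genes rose, also adjusted over the list alone (median 1.76, adjusted p = 2.65e-21; adjusted p = 0.0849 with an estimated correlation). Among them were Ccna2 (3.19), Ccnb2 (2.92), Aurkb (2.90) and the proliferation marker Mki67 (2.48). The p53 targets and growth arrest list had 12 rises and 1 fall among 19, also adjusted over the list alone (median 0.75, adjusted p = 1.82e-06, and 0.0239 with an estimated correlation). The largest changes were Cdkn1a (4.07) and Gadd45b (3.09). Stellate cell and matrix markers rose for 16 of 19 with 0 falls (17 adjusted over the list alone; median 1.35, adjusted p = 1.10e-10; adjusted p = 0.0947 with an estimated correlation). Among them were Timp1 (3.32) and Acta2 (2.54). Cytokines and chemokines had 16 rises and 1 fall among 24 (17 and 1 adjusted over the list alone; median 1.08, adjusted p = 3.41e-08; adjusted p = 0.124 with an estimated correlation). NRF2 targets had 14 rises and 1 fall among 22 (15 and 1 adjusted over the list alone; median 0.50, adjusted p = 3.28e-08; adjusted p = 0.134 with an estimated correlation). Interferon-stimulated genes rose for 13 of 21 with 0 falls, also adjusted over the list alone (median 0.94, adjusted p = 1.48e-06; adjusted p = 0.180 with an estimated correlation). Among them were Usp18 (2.44), Oas2 (1.97) and Oasl2 (1.83).

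Neutrophil markers in DEL had 8 rises and 1 fall among 13, also adjusted over the list alone (median 1.73, adjusted p = 0.000210; adjusted p = 0.134 with an estimated correlation). Among them were Mmp8 (3.82) and Csf3r (2.39). The endoplasmic reticulum and integrated stress response list had 9 rises among 24, also adjusted over the list alone (median 0.05, mean 0.61, adjusted p = 0.0221; adjusted p = 0.317 with an estimated correlation). Its rises were led by Psat1 (4.41), Fgf21 (3.48), the stress-induced transcription factor Atf3 (3.14) and Asns (1.52). Endothelial markers had 7 rises and 1 fall among 16 (8 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.0221; adjusted p = 0.469 with an estimated correlation). The largest rise was Lyve1 (1.34). Hepatocyte markers had a median of -0.04 with 1 rise and 5 falls among 12, also adjusted over the list alone (adjusted p = 0.304).

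Several metabolic lists were called lower in DEL. Fatty acid and triglyceride synthesis had 19 falls and 1 rise among 22, also adjusted over the list alone (median -1.21, adjusted p = 5.14e-10; adjusted p = 0.0947 with an estimated correlation). Among them were Elovl3 (-4.07), Thrsp (-2.51), Srebf1 (-2.44) and fatty acid synthase Fasn (-2.13). Urea cycle and amino acid catabolism had 24 falls among 27 (25 adjusted over the list alone; median -0.91, adjusted p = 1.10e-10; adjusted p = 0.134 with an estimated correlation). The largest fall was Otc (-2.57). Bile acid synthesis and transport had 19 falls among 26 (20 falls and 1 rise adjusted over the list alone; median -0.92, adjusted p = 1.05e-07; adjusted p = 0.0947 with an estimated correlation). Among them were Slco1a1, Cyp7a1 (-3.38), Cyp8b1 (-2.27) and Cyp7b1 (-2.11). Cholesterol synthesis had 17 falls among 20, also adjusted over the list alone (median -0.82, adjusted p = 1.55e-06; adjusted p = 0.308 with an estimated correlation). Coagulation and complement had 22 falls and 1 rise among 26 (24 and 1 adjusted over the list alone; median -0.54, adjusted p = 6.68e-07; adjusted p = 0.260 with an estimated correlation). Male-biased liver genes had 15 falls among 19, also adjusted over the list alone (median -1.57, adjusted p = 4.64e-08; adjusted p = 0.117 with an estimated correlation). Female-biased genes had 4 rises and 4 falls among 21 (median -0.05, mean 0.12, adjusted p = 0.895). Pericentral genes (7 falls and 1 rise among 15, 10 and 1 adjusted over the list alone; median -0.63, adjusted p = 0.0221; adjusted p = 0.479 with an estimated correlation) were called lower. So was oxidative phosphorylation (8 falls among 28, also adjusted over the list alone; median -0.17, adjusted p = 0.0395; adjusted p = 0.595 with an estimated correlation). Not called in DEL were CAR and PXR targets (2 rises, 5 falls of 16, median -0.05), fatty acid oxidation and PPARA targets (3 rises, 5 falls of 23), glucose metabolism (7 rises, 9 falls of 20), circadian clock (5 falls of 18), acute phase proteins (8 rises, 6 falls of 25) and the other lists. In all, 19 of 35 lists were called in DEL, 3 of them with an estimated correlation.

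In INS mice, TCDD raised the AHR battery while most of the wider response seen in the other lines was not called. Cyp1a1 rose by 4.85 ± 0.18 (adjusted p = 7.96e-27), from 7.48 ± 0.49 (SD, n = 5) to group means of 12.2 to 12.4, with every treated array (lowest 11.7) above every corn oil array (highest 7.94). Cyp1b1 rose by 6.25 ± 0.27, Ahrr by 2.90 ± 0.24, Tiparp by 2.80 ± 0.21, Nqo1 by 1.93 ± 0.28 and Cyp1a2 by 0.81 ± 0.09. Ahr (0.05 ± 0.11) and Aldh3a1 (0.00 ± 0.15) did not pass. The other large rises were the neuronal pentraxin Nptx1 (3.77), Ctrb1 (3.49), Ecel1 (3.34), the tubulin gene Tuba8 (2.82), Pcp4l1 (2.81) and Cyfip2 (2.78). The largest falls were Adgrf1 (-1.31), Arhgap6 (-1.04), Lor (-0.93), Arrdc3 (-0.93), Mrnip (-0.92), the clock repressor Nr1d1 (-0.89), Smagp (-0.78), Gabbr2 (-0.76), the phosphodiesterase Pde4b (-0.75) and the sorting receptor Sort1 (-0.73). The calls of several of these falls lay near the threshold. Leaving out 1 of the 22 INS arrays at a time, Nr1d1 lost its call in 15 cases, Gabbr2 in 4, Adgrf1 in 3, Arrdc3 in 2 and Mrnip, Smagp and Sort1 in 1 each, while Arhgap6, Lor and Pde4b kept theirs. The estimates moved little in these cases: Nr1d1 stood at -0.92 to -0.77, Gabbr2 at -0.77 to -0.68, Adgrf1 at -1.26 to -1.09, Arrdc3 at -0.88 to -0.78, Mrnip at -0.84, Smagp at -0.73 and Sort1 at -0.68. In all 120 features were called, 91 higher and 29 lower. The count was 328 with array weights and 192 without the 4 rWT arrays, which enter only the estimate of the spread. It was 77 without INS corn oil replicate 3 and 78 without replicate 5.

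AHR targets rose in INS for 11 of 16 with 0 falls, 13 adjusted over the list alone (median 0.91, adjusted p = 2.59e-67, and 7.02e-15 with an estimated correlation). The p53 targets and growth arrest list was called as well (median 0.27, adjusted p = 9.62e-07, and 0.0164 with an estimated correlation). Cdkn1a (2.24) was its 1 rise among 19, and 4 rose when adjusted over the list alone. The cell cycle list was called (median 0.57, adjusted p = 1.27e-14; adjusted p = 0.216 with an estimated correlation) although none of its 26 genes passed over all genes and 10 rose when adjusted over the list alone. Its largest values were Ccnb2 (1.07) and Ccna2 (1.06). NRF2 targets (1 rise among 22, 3 adjusted over the list alone; median 0.13, adjusted p = 5.80e-05; adjusted p = 0.591 with an estimated correlation) rose for Gstm3 (0.70). In the endoplasmic reticulum and integrated stress response list (median 0.12, adjusted p = 0.000197; adjusted p = 0.216 with an estimated correlation) 3 of 24 rose, 4 adjusted over the list alone, namely Psat1 (2.31), Atf3 (1.38) and Fgf21 (1.29) over all genes. Of these, Fgf21 lost its call in 12 of the 22 omissions of single INS arrays and Atf3 in 4, all 4 of them corn oil arrays, with estimates of 1.21 to 1.36 and 1.26 to 1.38 in those cases. Interferon-stimulated genes (median 0.12, adjusted p = 0.0198; adjusted p = 0.846 with an estimated correlation) rose for Usp18 alone of 21 (1.27), also adjusted over the list alone. Heat shock and protein folding (median 0.22, adjusted p = 0.00630; adjusted p = 0.216 with an estimated correlation) rose for Hspa8 alone of 12 (0.31), also adjusted over the list alone. Usp18 and Hspa8 each lost the call in 2 omissions, at 1.08 to 1.23 and 0.25 to 0.30. The median of the interferon-stimulated list was 0.24, 0.34, 0.13 and -0.15 from the lowest to the highest dose.

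Kupffer cell and macrophage markers were called higher in INS (median 0.12, adjusted p = 0.00196; adjusted p = 0.769 with an estimated correlation). Lymphocyte markers were called lower (median -0.21, adjusted p = 0.00355; adjusted p = 0.672 with an estimated correlation). In each, limma called 0 of 19 members, also adjusted over the list alone. From the lowest to the highest dose the macrophage median was 0.16, 0.42, 0.09 and -0.03. The lymphocyte median was -0.03, -0.02, -0.28 and -0.43. Gpnmb stood at 1.22 (adjusted p = 0.442) and Cd4 at -0.49. Of the lists called lower in rWT and DEL, these were not called in INS: bile acid synthesis and transport (median -0.12, adjusted p = 0.0554), fatty acid and triglyceride synthesis (0.03, adjusted p = 0.430), cholesterol synthesis (0.05, adjusted p = 0.429), urea cycle and amino acid catabolism (-0.12, adjusted p = 0.137) and coagulation and complement (-0.09, adjusted p = 0.206). Neutrophil markers (median 0.11, adjusted p = 0.429) and stellate cell and matrix markers (-0.02, adjusted p = 0.953) were not called either. In all, 9 of 35 lists were called, 2 of them with an estimated correlation.

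**Figure D2:**
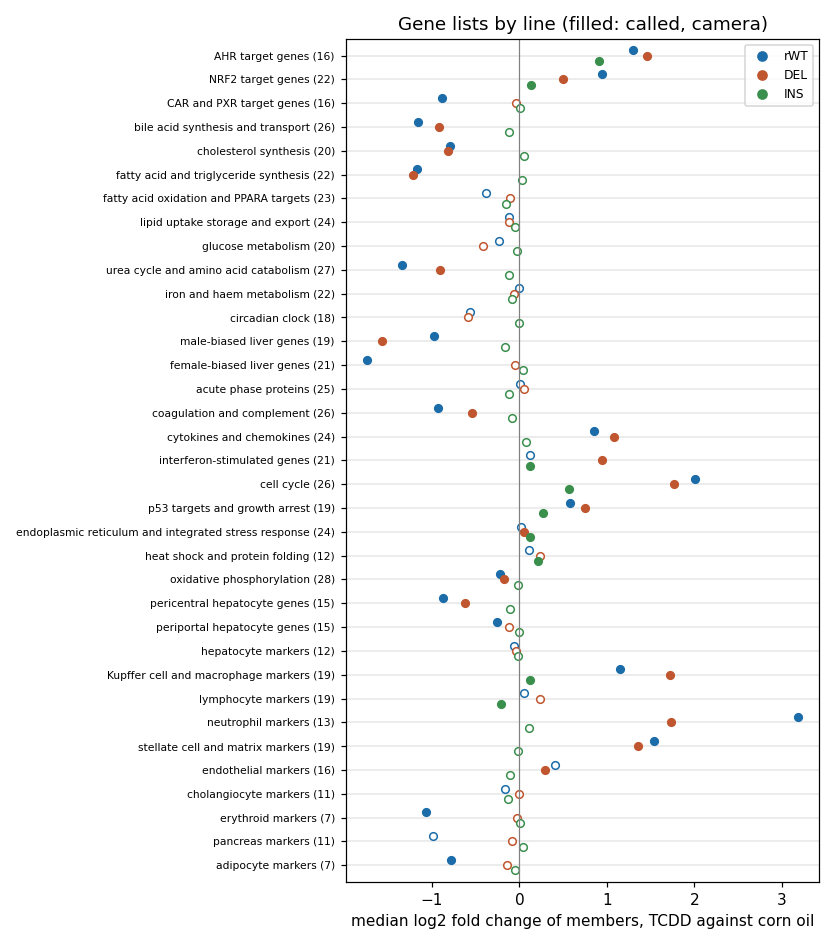
Median log2 TCDD effect of each gene list in rWT, DEL and INS mice, 1 point per list and line, filled where camera called the list at its preset correlation. The cell cycle list stands at 2.01, 1.76 and 0.57 and the urea cycle and amino acid catabolism list at -1.34, -0.91 and -0.12.

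By dose, the counts in rWT were 5039 features at 125 µg/kg (2920 higher), 6523 at 250 (3507 higher), 4950 at 500 (2776 higher) and 6018 at 1000 (3315 higher). The last count fell to 3855 without replicate 1 and 3548 without replicate 2, each of which leaves a lone array assumed to vary like the other groups. In DEL they were 3628 (1989 higher), 4747 (2434 higher), 5797 (3077 higher) and 5709 (3028 higher). After median centring the counts were 8131, 10117, 6952 and 10046 in rWT, of which 1902, 2448, 1791 and 2286 were higher, and 6799, 10649, 10732 and 12232 in DEL, of which 1390, 1636, 2057 and 1974 were higher. In INS they were 17 (17 higher), 30 (27 higher), 49 (44 higher) and 216 (119 higher), and quantile normalization gave 17 at 125 (15 higher) and 183 at 1000 (120 higher). The fit without the 4 rWT arrays gave 28, 54, 77 and 344 in INS, the last with 173 higher and 171 lower. In rWT that fit gave 5178, 6486, 5293 and 6229, of which 2689, 3222, 2783 and 3094 were higher. Of the rWT features called with all arrays, 3706, 4926, 3706 and 4707 kept call and sign in it. With the female pattern as a covariate the rWT counts were 3010, 4625, 3664 and 4244. Array weights gave 29, 74 and 109 in INS at the 3 lower doses, and 8418 in rWT and 6150 in DEL at 125. Single arrays moved the INS counts: at 250 the count was 18, 50 and 16 without replicates 1, 2 and 3; at 500 it was 23 and 30 without replicates 3 and 4 and 32 without corn oil replicate 3. At 1000 it was 137 and 123 without replicates 2 and 3 and 132 and 121 without corn oil replicates 1 and 5.

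**Figure D3:**
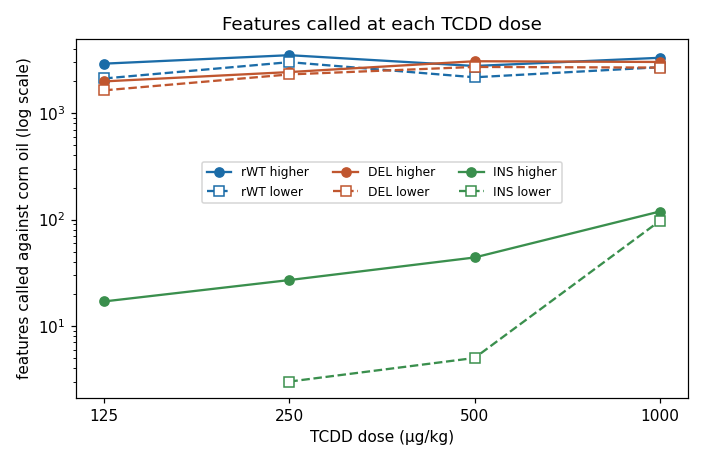
Number of features called against corn oil at each TCDD dose (µg/kg) in the 3 lines, higher and lower shown apart. In INS 17 to 216 features were called, in DEL 3628 to 5797 and in rWT 4950 to 6523.

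The AHR genes Tiparp and Ahrr were called at the lowest dose in all 3 lines. In INS Tiparp rose by 2.38, 2.71, 2.83 and 3.29 from the lowest to the highest dose and Ahrr by 2.35, 2.72, 3.04 and 3.47, while Nqo1 stood at 1.55 at 125 µg/kg (adjusted p = 0.0873) and rose by 1.95, 2.06 and 2.17 at the others. The slope on log2 dose among treated mice was tested as well, with counts that depended on the setting. The slopes of Tiparp, Ahrr and Nqo1 in INS did not pass. In INS 9 features were called: Nr1d1 (-0.53 ± 0.09 per doubling of dose, adjusted p = 0.0176), Arrdc3 (-0.43), Slc8b1 (-0.36), Tcp11l2 (-0.34), Spata13 (-0.29) and the clock gene Cry1 (0.36 ± 0.07, adjusted p = 0.0293) were the nameable ones with the largest slopes. Leaving out 1 of the 17 treated INS arrays at a time, the call was lost in 12 cases for Tcp11l2, 10 for Spata13, 9 for Arrdc3, 4 for Cry1, 2 for Slc8b1 and 1 for Nr1d1. The slopes in those cases were -0.36 to -0.31 for Tcp11l2, -0.30 to -0.26 for Spata13, -0.44 to -0.38 for Arrdc3, 0.31 to 0.37 for Cry1, -0.33 to -0.32 for Slc8b1 and -0.50 for Nr1d1. Nr1d1 stood at -0.08, -0.66 and -1.09 at the 3 lower doses, none passing, and fell by 1.72 at 1000 µg/kg. In rWT 6 were called, among them Pkp1 (-0.40), Htr2a (0.34) and Bcl2l15 (0.34), which lost their call in 1, 9 and 8 of 12 such omissions, at -0.37, 0.28 to 0.39 and 0.32 to 0.36. In DEL limma called 0, with 2260 features at an unadjusted p under 0.05, against 746 in rWT and 1352 in INS.

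The slope counts rested on single arrays, on scaling and on the model. Array weights gave 247 in rWT and 577 in DEL, and the fit without the 4 rWT arrays gave 14 in rWT, 72 in DEL and 18 in INS. With only the arrays of each line the count was 0 in rWT and 2 in INS, and with the replicate block it was 16 in INS. In DEL the count was 330 without 125 replicate 3, 39 without 500 replicate 3, 17 without 1000 replicate 4, 8 without 250 replicate 3 or 1000 replicate 3, 7 without 250 replicate 2 and 5 without 500 replicate 4. In rWT it was 13 without 500 replicate 4, 3 without 250 replicate 1 or 2, and 2 without 125 replicate 2 or 3, 500 replicate 1, 2 or 3, or 1000 replicate 2. In INS it was 17 without 1000 replicate 4, 5 without 125 replicate 3, 250 replicate 4 or 1000 replicate 3, 4 without 125 replicate 4 or 500 replicate 1, 2 without 1000 replicate 2, 1 without 1000 replicate 5 and 0 without 125 replicate 1. Quantile normalization gave 2 (1 higher) in rWT, 4 (1 higher) in DEL and 0 in INS, and median centring 3 (2 higher), 5 (3 higher) and 3 (1 higher).

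**Figure D4:**
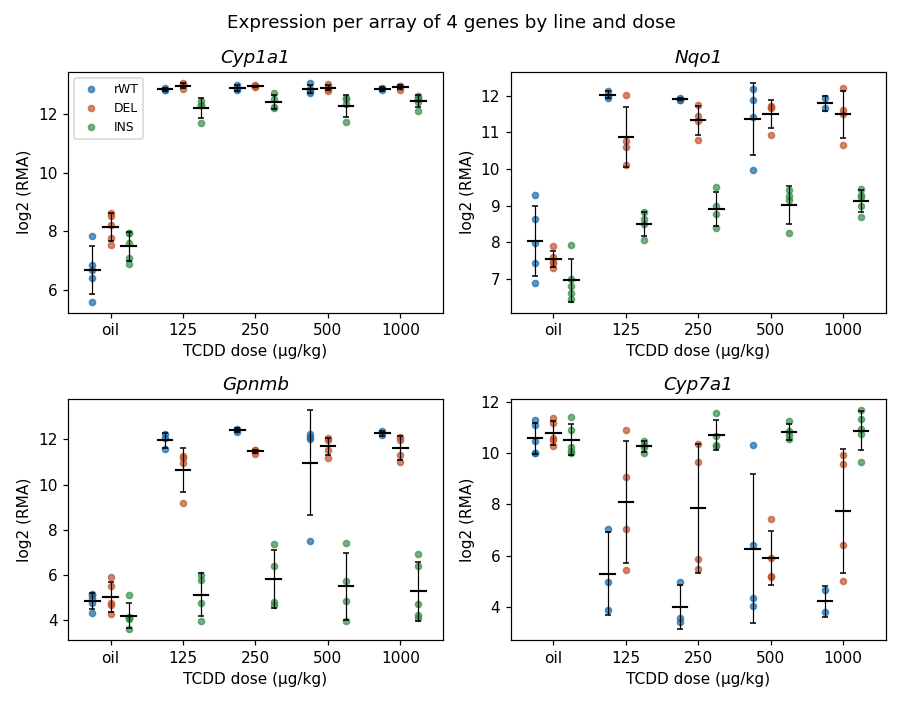
Log2 expression of Cyp1a1, Nqo1, Gpnmb and Cyp7a1 by TCDD dose (µg/kg) in the 3 lines, with 1 point per array, the bar at the group mean and error bars of 1 SD. Treated Cyp1a1 means are 12.84 to 12.97 in rWT and DEL and 12.2 to 12.4 in INS, while the averaged Gpnmb effect is 7.04, 6.32 and 1.22.

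The direct comparison of INS with DEL asks which effects differ in size. The effect on the macrophage gene Gpnmb was lower in INS by a difference of -5.10 ± 0.70 (adjusted p = 1.41e-06), as were those on the platelet factor gene Pf4 (-3.68), Mmp8 (-3.66), Ly6d (-3.61) and the glutathione peroxidase Gpx2 (-3.58). Effects on Hsd3b5 (6.07 ± 1.15, adjusted p = 0.000136), Serpina4-ps1 (4.55), Slco1a1 (4.37), Car1 (3.93) and Sult2a8 (3.93) were less negative in INS. Within the AHR battery, Nqo1 (-1.82, adjusted p = 0.000772), Ahrr (-1.41, adjusted p = 0.00284) and Tiparp (-1.08, adjusted p = 0.00934) rose less in INS, whereas the difference was 0.05 for Cyp1a1 (adjusted p = 0.947), -0.27 for Cyp1b1 (adjusted p = 0.733) and 0.11 for Cyp1a2 (adjusted p = 0.667). Cyp1a1 and Cyp1a2 lay near the top of the array range after TCDD, so a difference in their rise could not be read in full. Treated Cyp1b1 means were 10.1 to 10.9 in INS and 12.0 to 12.4 in DEL. The like rise rests on corn oil levels of 4.26 and 5.67, and levels also carry the offset between lines. In all 2978 features differed, 1146 higher and 1832 lower in INS. Quantile normalization gave 3419 (1734 higher) and median centring 6423 (5091 higher).

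By list, the INS effect was below that in DEL for Kupffer cell and macrophage markers (18 of 19 lower, 19 adjusted over the list alone; median -1.62, adjusted p = 1.14e-24, and 0.0124 with an estimated correlation). It was also below for cell cycle genes (19 of 26, 23 adjusted over the list alone; median -1.22, adjusted p = 1.25e-15; adjusted p = 0.119 with an estimated correlation). The same held for stellate cell and matrix markers (13 of 19, 17 adjusted over the list alone; median -1.26, adjusted p = 1.15e-13; adjusted p = 0.0764 with an estimated correlation) and NRF2 targets (8 of 22, 10 adjusted over the list alone; median -0.44, adjusted p = 2.79e-06; adjusted p = 0.222 with an estimated correlation). AHR targets were lower for 6 of 16 (8 lower and 1 higher adjusted over the list alone; median -0.33, adjusted p = 0.00552; adjusted p = 0.126 with an estimated correlation). The INS effect was above that in DEL for fatty acid and triglyceride synthesis (17 of 22, 20 adjusted over the list alone; median 1.19, adjusted p = 5.09e-14; adjusted p = 0.0586 with an estimated correlation). It was above as well for urea cycle and amino acid catabolism (17 of 27, 22 adjusted over the list alone; median 0.84, adjusted p = 4.58e-11; adjusted p = 0.126 with an estimated correlation) and bile acid synthesis and transport (13 of 26, 15 adjusted over the list alone; median 0.65, adjusted p = 4.67e-07; adjusted p = 0.119 with an estimated correlation). In all 18 of 35 lists were called, 1 with an estimated correlation.

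INS against rWT gave a like picture. Cyp7a1 (5.77 ± 1.04, adjusted p = 3.73e-05), Sult2a8 (5.75), Car3 (5.63), Inmt (5.61) and Cyp2b9 (4.96) had higher estimates in INS than in rWT, and Cyp2b9 lost its call without the 4 arrays (2.01, adjusted p = 0.283). Gpnmb (-5.82 ± 0.71, adjusted p = 6.11e-08), Mmp8 (-5.63), Cyp21a1 (-5.47), Il1r2 (-5.38) and Pf4 (-5.12) had lower estimates. None of these 10 genes was called in INS itself. Neutrophil markers were lower in INS for 9 of 13, also adjusted over the list alone (median -2.90, adjusted p = 4.54e-09; adjusted p = 0.0748 with an estimated correlation, and 0.00784 without the 4 arrays). Cell cycle genes were lower for 19 of 26 (24 adjusted over the list alone; median -1.53, adjusted p = 1.21e-15; adjusted p = 0.121 with an estimated correlation). Urea cycle and amino acid catabolism was higher for 20 of 27 (21 adjusted over the list alone; median 1.27, adjusted p = 2.54e-13; adjusted p = 0.121 with an estimated correlation). In all 4413 features differed, 1784 higher and 2629 lower. Leaving out the 4 arrays, 4710 differed, of which 3281 were shared, and 2505 with the covariate, while median centring gave 6334 (4568 higher). Of 35 lists 22 were called, 0 with an estimated correlation,.

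DEL against rWT gave 235 features, 132 higher and 103 lower. The largest positive differences were in female-biased or sex-dependent liver genes, Cyp2b9 (5.61), Sult3a1 (3.74), Slc22a26 (3.73), A1bg (3.72) and Cyp2a22 (2.97). None of the 5 was called without the 4 arrays, at 2.66, 0.10, 0.60, -0.26 and 0.76. Cyp4a12b (-3.59) likewise went to 0.06. The other 4 negative differences kept their call: Ppbp (-3.20 ± 0.56, and -2.56 without the 4 arrays, adjusted p = 0.000554), Il1r2 (-3.13 ± 0.46, and -3.40, adjusted p = 2.11e-08), Dpep2 (-2.52 ± 0.48, and -2.57, adjusted p = 7.55e-05) and S100a8 (-2.49 ± 0.52, and -2.20, adjusted p = 0.0385). Neutrophil markers rose less in DEL for 4 of 13 (7 adjusted over the list alone; median -1.81, adjusted p = 6.24e-08; adjusted p = 0.107 with an estimated correlation). Without the 4 arrays this was 6 of 13, again 7 adjusted over the list alone, with a median of -1.83 (adjusted p = 2.81e-09, and 0.00719 with an estimated correlation). Interferon-stimulated genes rose more in DEL for 4 of 21 (10 adjusted over the list alone; median 0.58, adjusted p = 1.99e-11; adjusted p = 0.107 with an estimated correlation). With those arrays left out, it was 1 (4 adjusted over the list alone; median 0.42, adjusted p = 0.00354; adjusted p = 0.735 with an estimated correlation). The female-biased list (5 higher of 21, 14 higher and 1 lower adjusted over the list alone; median 2.04, adjusted p = 5.06e-12; adjusted p = 0.107 with an estimated correlation) had a median of -0.06 without the 4 arrays (adjusted p = 0.817).

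The estimated effect on Cyp1a1 was smaller in DEL than in rWT (-1.39, adjusted p = 0.00142), and that on Cyp1a2 too (-0.49, adjusted p = 0.0441). Treated Cyp1a1 means were 12.84 to 12.97 in both lines, near the top of the array range, so this difference reflects the corn oil levels of 6.67 in rWT and 8.13 in DEL and is not read as a smaller induction. Leaving out the 4 arrays, the rWT effects were 5.59 for Cyp1a1 and 0.70 for Cyp1a2, against 4.80 and 0.70 in DEL. Leaving out the 4 arrays, limma called 0 of the 16 AHR targets in this comparison, also adjusted over the list alone. The count of 235 was sensitive to the model and to single arrays. It was 1000 with array weights, 106 with only the arrays of the lines compared and 82 with the replicate block, and it was 585 without rWT TCDD 500 replicate 4, 394 without rWT corn oil replicate 1, 147 without rWT corn oil replicate 3 and 155 without DEL corn oil replicate 5. With the 4 arrays left out, 227 features were called, of which 96 were shared with the 235, and 27 with the covariate. Of 35 lists 17 were called, 0 with an estimated correlation, 11 with the replicate block and 7 without the 4 arrays.

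Across features, the averaged effects of DEL and rWT correlated at r = 0.87 (rho 0.77, slope of DEL on rWT 0.73), or 0.91 without the 4 arrays. Those of INS and DEL correlated at 0.55 (rho 0.43, slope of INS on DEL 0.19) and those of INS and rWT at 0.47 (rho 0.38). Genes are not independent replicates, so no p is given. DEL and rWT shared 2892 features higher in both, where independent lists would share 714, and 2384 lower in both, where they would share 759, with 14 in opposite directions. Of the 91 features higher in INS 87 were also higher in DEL, of the 29 lower 26 were also lower, and 0 were opposite. In all 3 lines 83 features were higher and 22 lower.

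**Figure D5:**
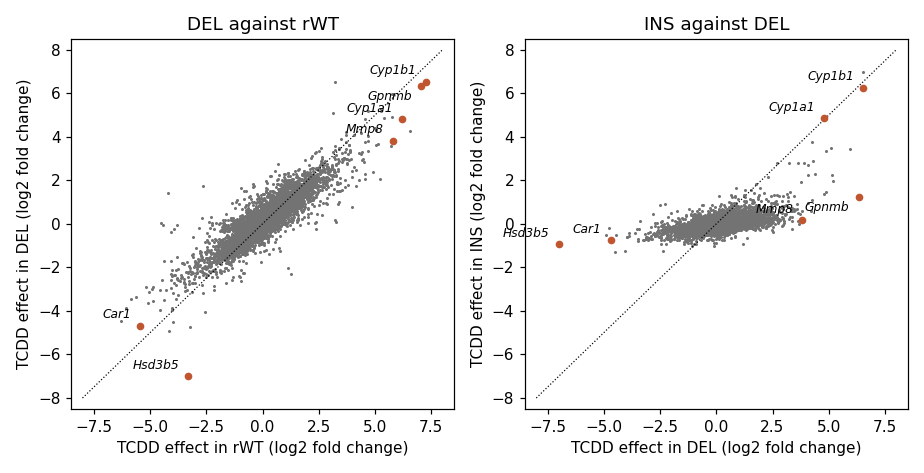
Averaged log2 TCDD effect per feature, DEL against rWT and INS against DEL, 1 point per feature with the named genes labelled. DEL and rWT effects correlate at 0.87, and INS and DEL effects at 0.55, with Cyp1a1 at 4.80 in DEL and 4.85 in INS.

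In corn oil mice the lines were compared without TCDD. The median difference over all features was 0.24 for DEL minus rWT, -0.29 for INS minus rWT and -0.54 for INS minus DEL, and differences are to be read against it. Between DEL and INS, the chaperone gene Hsp90aa1 was higher in INS by 0.95, or 1.48 beyond the median difference, followed by the olfactory receptor genes Olfr45 (0.59, or 1.13 beyond), Olfr1303 (0.58, or 1.11) and Olfr857 (0.51, or 1.05) and the histone gene H2bc1 (0.48, or 1.01). Stfa2l1 (-3.42, or -2.88 beyond), the T cell receptor segment Trav12-1 (-2.00, or -1.46), the Y-linked Sry (-1.88, or -1.34), Adi1 (-1.88, or -1.34) and Fosl1 (-1.82, or -1.28) were lower in INS. All 10 passed after quantile normalization and after median centring too. Single arrays mattered for 3 of them: Hsp90aa1 stood at 0.37 without INS corn oil replicate 3 (adjusted p = 0.196), and Olfr857 and Olfr1303 lost their call in 5 and 4 of 10 omissions, at 0.35 to 0.49 and 0.44 to 0.51.

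Against rWT, the largest differences of both other lines were in sex-dependent genes and were smaller without the 4 arrays. Values here are as fitted and hold the offset between lines, a median of 0.24 for DEL and -0.29 for INS with all arrays. For DEL minus rWT these were Hsd3b5 (5.42), Cyp4a12b (4.68), Cyp4a12a (4.03), Eif2s3y (3.77), Elovl3 (3.26), Cyp2b9 (-5.27), Sult2a2 (-5.02), Xist (-4.84), Cyp2b13 (-4.32) and Slc22a26 (-4.25), none of them called without the 4 arrays. In that order they then stood at 0.63, 0.78, 0.14, 0.19, -0.12, -1.83, 0.68, 0.0208, 0.29 and -0.81. For INS minus rWT Hsd3b5 (5.12), Cyp4a12b (3.91), Cyp4a12a (3.47), Eif2s3y (3.30), Elovl3 (3.04), Sult2a2 (-5.62), Cyp2b9 (-5.44), Xist (-4.99) and Cyp2b13 (-4.98) lost their call in the same way. They then stood at 0.33, 0.0105, -0.42, -0.27, -0.33, 0.0839, -2.00, -0.13 and -0.37. A lost call in this smaller set of arrays does not show that no difference remained, least of all for Cyp2b9. Slc22a27 (-4.46) kept it at -2.45 (adjusted p = 0.000826).

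The counts in corn oil mice rest on scaling: 7600 features differed for DEL minus rWT (7240 higher), 8825 for INS minus rWT (296 higher) and 15950 for INS minus DEL (13 higher). Quantile normalization gave 2823 (1629 higher), 3240 (1825 higher) and 1720 (877 higher), and median centring 2540 (2029 higher), 4968 (4193 higher) and 1511 (1029 higher). Once the 4 arrays were left out, the first count was 3501 and the second 6027. By camera 13, 12 and 29 lists were called, of which 0, 0 and 6 also with an estimated correlation, and after quantile normalization 5, 4 and 0. Hepatocyte markers were 1 of the 6 in INS minus DEL, with a median of -0.03 against -0.54 over all features (adjusted p = 1.85e-08, and 0.0227 with an estimated correlation). Female-biased genes were lower in DEL than in rWT for 13 of 21 and higher for 1, also adjusted over the list alone (median -1.70, adjusted p = 5.36e-17; adjusted p = 0.154 with an estimated correlation), and no list was called by camera in that comparison without the 4 arrays. For INS minus rWT the lists called rose from 12 to 25 in the same fit.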

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

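The tests of spread, of separate normalization for neutrophil markers and of other splits were written before the results were seen, and all other tests here were chosen only after the result was seen.

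INS mice had 120 features called under TCDD against 7245 in DEL, while Cyp1a1 was called in both, at 4.85 and 4.80, a likeness that carries little information because treated Cyp1a1 lay near the top of the array range in DEL. Larger spread between INS arrays is argued against by a residual SD of 0.976 times that of DEL. A different distribution of array values between lines is argued against by 3419 features called for INS minus DEL after quantile normalization. That step cannot undo background correction or probe processing done per line, so separate normalization as such is not excluded. One common factor for every gene is argued against by the AHR targets with a DEL effect of at least 1, whose median INS to DEL ratio was 0.673 against 0.129 over all 1707 such features, where the central 95% of random sets of equal size ended at 0.264. That restriction was set after a first run over all 13 AHR targets called in DEL had been seen, which gave 0.673 against 0.153 where that interval ended at 0.325. The 6 targets with a DEL effect of at least 1 and all group means under 12 had a median of 0.634, where that interval ended at 0.298, which argues against the array ceiling, while a receptor variant that keeps direct targets, the liver dose and a later time stay open.

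The 4 rWT arrays labelled male have high Xist and low Y-linked genes. Mixing with male RNA is argued against by Eif2s3y, which on the linear scale reached at most 3.65% of the lowest other array. Samples of female mice may explain them: for 3 of 3 such corn oil arrays the score of female-biased minus male-biased genes (0.25 to 3.63) lay above all 12 other corn oil arrays (-6.47 to -3.88). Whether animals were female or samples were exchanged stays open.

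The TCDD effect differed between DEL and rWT for 235 features. The female pattern may account for the female-biased list, whose median difference was -0.0641 without the 4 arrays. It does not account for neutrophil markers, with a median of -1.83 without them. A different distribution of array values between lines does not either, with -1.83 after quantile normalization. That step cannot undo probe processing done per line. What remains open is whether the receptor variant or another difference between the lines lowered the neutrophil response.

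Differences between lines in the TCDD effect numbered 4413 for INS minus rWT and 2978 for INS minus DEL besides the 235. For DEL minus rWT the largest were Cyp2b9 5.61, Sult3a1 3.74, Slc22a26 3.73, A1bg 3.72, Cyp2a22 2.97, Cyp4a12b -3.59, Ppbp -3.20, Il1r2 -3.13, Dpep2 -2.52 and S100a8 -2.49. For INS minus rWT they were Cyp7a1 5.77, Sult2a8 5.75, Car3 5.63, Inmt 5.61, Cyp2b9 4.96, Gpnmb -5.82, Mmp8 -5.63, Cyp21a1 -5.47, Il1r2 -5.38 and Pf4 -5.12. For INS minus DEL they were Hsd3b5 6.07, Serpina4-ps1 4.55, Slco1a1 4.37, Car1 3.93, Sult2a8 3.93, Gpnmb -5.10, Pf4 -3.68, Mmp8 -3.66, Ly6d -3.61 and Gpx2 -3.58, and the Kupffer cell and macrophage list had a median of -1.62.

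Of 156 group tests 13 set a value far from its group, where chance would give about 1 in 20, or 7.8. On rWT TCDD 500 replicate 4 they were Ahrr 8.26, Xist 11.4, Eif2s3y 3.35, Uty 3.81 and Kdm5d 4.06. In DEL they were Ahr 9.91 (125 replicate 1), Aldh3a1 6.15 (250 replicate 3) and Nqo1 10.9 (500 replicate 3). In INS they were the array mean of 5.66 (corn oil replicate 1) and of 5.58 (1000 replicate 3), Xist 2.78 (125 replicate 3), Eif2s3y 8.15 (250 replicate 4) and Kdm5d 6.67 (1000 replicate 5).

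Other splits of the arrays into groups of the same sizes were counted with limma in the same way, with the real split included among 100, or 56 where only so many exist. For the differences between lines, a line effect common to all doses was first removed from each feature. Lines were then exchanged within each dose. For the averaged effect 1 split reached the real count in rWT (highest other 7855), 1 in DEL (3541) and 2 in INS (703). At 125, 250 and 500 µg/kg in rWT it was 1 of 56, 1 of 56 and 1 of 100 (3095, 3692 and 4371). In DEL it was 1 at each dose (2046, 3099, 4062 and 3818), and in INS 1, 2, 1 and 2 (9, 197, 21 and 700). For the differences between lines it was 1 each (215, 1974 and 1869), and for corn oil mice 1 each (3501, 3163 and 8207). At this number of splits, at most 2 reached the real count for these 20 counts, the real split included. For the slopes more did, 17 in rWT, 100 in DEL and 6 in INS (1469, 1427 and 1726), so chance stays open there. For corn oil mice the splits cannot decide, because a split that mixes the lines loses the offset between them. For DEL minus rWT the highest other count of 215 lay close to the real 235. Splits that call several times the real count, as 703 against 120 in INS, point to a structure of the samples. Ranks among splits therefore argue against chance outside the slopes and corn oil mice but do not exclude it.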

How the results depend on the processing

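The tests without the 4 rWT arrays and with the female pattern as a covariate were chosen after seeing the data. Of 446 values of named genes, 12 reversed without the 4 arrays, 6 with the covariate and 1 with the replicate block, and none under median centring or quantile normalization. Leaving out each array in turn gave 9020 gene values, of which 255 lost and 7 gained their call and 0 reversed. Of 315 list values 147 of 160 calls were lost with an estimated correlation. Except where a setting tests fewer genes or uses fewer arrays, the cause was not tested.

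Median centring gave 13735 (rWT) and 13835 (DEL) averaged, 8131, 10117 and 10046 in rWT at 125, 250 and 1000 µg/kg, and 6799, 10649, 10732 and 12232 in DEL. It gave slopes of 3, 5 and 3 in rWT, DEL and INS, 6423 for INS minus DEL, 2540, 4968 and 1511 in corn oil mice, and 7 and 8 lists for corn oil INS minus rWT and INS minus DEL. Quantile normalization gave slopes of 2, 4 and 0, corn oil counts of 2823, 3240 and 1720 and 5, 4 and 0 lists.

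A minimum change of 1 gave 2222, 1707 and 41 averaged, 1920, 2462, 1736 and 2681 in rWT by dose, 1316, 1666, 2163 and 1820 in DEL, and 32 and 75 in INS at 500 and 1000. It gave 147, 1804 and 1302 differences between lines and 276, 826 and 968 in corn oil mice. Array weights gave 328 averaged in INS, 8418 and 6150 at 125 in rWT and DEL, 29, 74 and 109 in INS at 125, 250 and 500, slopes of 247 and 577 in rWT and DEL, and 1000 for DEL minus rWT.

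Without the 4 arrays INS had 192 averaged and 28, 54, 77 and 344 by dose, slopes were 14, 72 and 18, and corn oil DEL minus rWT was 3501. Lists were 7 for DEL minus rWT, and 0 and 25 for corn oil DEL minus rWT and INS minus rWT. The covariate gave 3010 in rWT at 125, 27 for DEL minus rWT, 2505 for INS minus rWT and 4857 for corn oil DEL minus rWT. The filter on the 40th percentile gave slopes of 1 and 5 in rWT and DEL and corn oil counts of 2610, 5116 and 8603. Only the arrays of the lines compared gave slopes of 0 and 2 in rWT and INS and 106 for DEL minus rWT. With 1 feature per symbol the rWT slope was 2. The replicate block gave 16 for the INS slope, and 82 features and 11 lists for DEL minus rWT. An estimated correlation left 1, 3, 2, 0, 0, 1, 0, 0 and 6 lists.

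Without the 4 arrays these reversed: A1bg (-0.26) and Cyp4a12b (0.0643) for DEL minus rWT, A1bg (0.0345) and Retn (0.00921) in rWT, corn oil DEL minus rWT Elovl3 (-0.12), Sult2a2 (0.68), Xist (0.0208) and Cyp2b13 (0.29), and corn oil INS minus rWT Cyp4a12a (-0.42), Eif2s3y (-0.27), Elovl3 (-0.33) and Sult2a2 (0.0839). With the covariate, corn oil DEL minus rWT Sult2a2 (0.11), Xist (0.17) and Cyp2b13 (0.48) and INS minus rWT Cyp4a12a (-0.23), Eif2s3y (-0.27) and Xist (0.0193) reversed. With the block, Cpb1 in rWT (0.0539) did. The corn oil values hold the offset between lines, a median of -0.29 for INS minus rWT with all arrays. Eif2s3y and Elovl3 lay near it in that comparison, so their change of sign is not read as a reversed difference.

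Reversed lists are given with adjusted p. Without the 4 arrays they were female-biased in rWT (0.951), fatty acid oxidation (0.635), male-biased (0.0635) and female-biased (0.817) for DEL minus rWT, male-biased for corn oil DEL minus rWT (0.457), and for corn oil INS minus rWT fatty acid oxidation (0.0179), female-biased (0.108) and interferon-stimulated genes (0.0455). With the block, pancreas markers reversed for DEL minus rWT (0.222) and INS minus rWT (0.483). For corn oil INS minus rWT, quantile normalization reversed acute phase (0.811), periportal (0.983) and hepatocyte (0.927), and median centring acute phase (0.827). For corn oil INS minus DEL, quantile normalization reversed NRF2 (0.758), CAR and PXR (0.941), bile acid (0.912), cholesterol (0.764), fatty acid and triglyceride synthesis (0.764), fatty acid oxidation (0.758), glucose (0.758), urea cycle (0.941), circadian (0.941), male-biased (0.758), coagulation (0.912), interferon-stimulated (0.941), cell cycle (0.941), stress response (0.764), pericentral (0.941) and periportal (0.941). Median centring there reversed circadian (0.860), male-biased (0.971), female-biased (0.868), interferon-stimulated (0.719), cell cycle (0.236), neutrophil (0.0492) and pancreas (0.868).

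Leaving out each array gave 7836 to 9105 averaged in rWT, 6306 to 7873 in DEL and 77 to 150 in INS. By dose it gave 3690 to 5009, 4761 to 6469, 3655 to 6107 and 3548 to 6057 in rWT, 2470 to 3921, 3592 to 5405, 4822 to 5747 and 4346 to 5941 in DEL, and 13 to 22, 16 to 50, 23 to 70 and 121 to 223 in INS. Slopes were 2 to 13, 0 to 330 and 0 to 17. Differences between lines were 147 to 585, 3961 to 5036 and 2413 to 3297, and corn oil counts 6524 to 8020, 7771 to 8362 and 15050 to 15595. Correlations were 0.839 to 0.887 for DEL with rWT, 0.420 to 0.490 for INS with rWT and 0.501 to 0.599 for INS with DEL.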

Other observations

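Among the 83 features higher in all 3 lines, single genes are given here that were chosen after their values were seen, with no test of a shared function. The transcription factor gene Myc rose by 2.34 in rWT, 1.96 in DEL and 1.65 in INS, and the mitochondrial folate enzyme Mthfd2 by 1.85, 1.92 and 1.33. The ribosome assembly gene Nop56 rose by 1.29, 1.26 and 0.83 and the amino acid transporter subunit Slc3a2 by 1.54, 1.45 and 0.85. The glucuronidation enzyme gene Ugt1a9 rose by 1.37, 2.29 and 2.13. Insl6 rose by 4.70, 4.06 and 2.71, and the cell division gene Ube2c by 3.35, 2.79 and 1.27. Among the 22 lower in all 3 lines, the growth arrest gene Gas1 fell by 2.31, 1.85 and 0.61 and Gcnt4 by 1.47, 1.75 and 0.62.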
